A study of Mus musculus with 18 samples.

How the data were processed

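The libraries measure total RNA from slices of hippocampus and cortex of male C57BL/6N mice, WT or Fmr1 KO, at postnatal day 28 to 35. Per the labels' protocols, 10 slices pooled from 2 or 3 mice made up each replicate, tissue was homogenised without detergent, cleared at 2000 g and 10000 g, and only then given 1% NP-40. Part of that lysate was kept as input and the rest went onto 15 to 45% sucrose gradients, from which medium and heavy pools were chosen by FMRP immunoblot. Input, medium and heavy of 1 replicate number within a genotype and treatment therefore share a lysate. Whether equal numbers in WT and KO share a preparation is not given in the sources used here, and the fit does not pair them. RNA per fraction was not given in the sources used here, so absolute amounts cannot be compared.

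The submitters' processing notes name Trimmomatic 0.32, Bowtie2 2.1.0, RSEM 1.2.11 and DESeq2 1.16.1 with mm10, without roles or order. The deposited count table holds estimated counts (expected counts) for 13973 genes, of which 0 of 251514 values are whole within 1e-06. They equal the values of the other deposited table times 1 factor per gene and 1 per library, so either table could have been computed from the other. The other deposited table holds a score, called TPM by the authors, of which 10 of 18 columns sum to more than TPM values can, so it is called rescaled TPM here. How genes were selected and whether batches were adjusted is not given in the sources used here. If they were adjusted, the spread between replicates is understated. The lowest rescaled TPM was 1.004 to 1.043 in vehicle and HHT replicate 1 libraries, and 0.7722 to 0.9041 in HHT replicate 2 libraries of both genotypes. The reason was not tested. If HHT replicate 2 is a separate batch, HHT against vehicle holds that batch on the HHT side only. Mitochondrially encoded mRNAs are absent, so that list of 26 names had 0 measured genes and was not tested.

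Counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling) as 12 group means over all 18 libraries, leaving 6 residual degrees of freedom and a prior of 7.36. The 6 HHT groups supply the spread, and a vehicle group of 1 library is assumed to vary like them. The low-count filter of edgeR kept all 13973 genes. Benjamini-Hochberg adjustment was applied within each of 15 comparisons at 0.05, and all tests are 2-sided. A comparison averaged over genotypes weighs them equally, and medium/input or heavy/input is a difference of log2 values between fractions. Totals ran from 6226237 to 13834652 counts per library, and the median SE over genes ran from 0.14 to 0.37 on the log2 scale across comparisons.

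Gene lists, 29 in number, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the lists of a comparison, and 28 had at least 3 measured genes. Members were also counted past 0.05 over all genes and adjusted over the list alone. The lists cover FMRP-bound mRNAs, chromatin modifiers, splicing factors, autism risk genes, ribosomal proteins, translation factors, the respiratory chain, immediate early genes, snoRNA host genes, the integrated stress response, chaperones, inflammatory genes, nuclear noncoding RNAs, ER folding, the proteasome, synaptic genes, cell type and region markers, blood and mitochondrially encoded mRNAs. The FMRP-bound list is a selection from published brain crosslinking data. Lists overlap in part, since the FMRP-bound, autism, chromatin and synaptic lists share genes, and brain neurons and glia express most of them. KO and WT vehicle libraries were compared by list medians only. Percentiles among 10000 random lists from 20 bins of expression were computed for them but carry no spread between libraries, and with 1 library a side they are not used here. Percentiles among lists matched on coding length place a list among other genes and carry no such spread either.

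Genes named in the text follow a rule: per comparison up to 10 with the largest rise and 10 with the largest fall among genes past 0.05 with a mean of at least 5 CPM and no overlap between the libraries of the 2 sides (dropped for differences of ratios and interactions), without predicted gene models, plus up to 4 genes per list discussed by smallest adjusted p, plus Fmr1, Fxr1, Fxr2 and Setd2. The groups, comparisons, lists, this rule and most other ways of testing were set before the data were examined. These other ways were DESeq2 1.42.0, RLE factors, total counts, no filter, each HHT lysate left out, fits on fewer libraries, each genotype alone, blocks for replicate number or lysate, and for lists an estimated correlation and the rotation test fry. Chosen after seeing the data were limma on log2(rescaled TPM + 1), the mean of the 3 fractions per lysate, HHT replicates 1 or 2 alone, and camera with a lysate block.

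Coding sequences came from GENCODE M21, which is built on GRCm38, the assembly that mm10 denotes. Of the 13973 genes 96.8% were matched to a coding transcript, 13066 by symbol and 457 by synonym. A hydrophobic segment was called where the mean Kyte-Doolittle hydropathy over 19 residues reached 1.6. Random lists matched on coding length used 20 bins. The pipeline was tested on simulated data with 200 changed genes of 13973: edgeR recovered 140 for KO against WT in input with 7 false calls, 141 for HHT against vehicle in heavy with 13, 103 for the KO to WT difference in medium/input with 9, and 69 for the interaction in heavy with 3. Of 2-fold changes it recovered 76%, 72%, 34% and 10% in these 4 cases. Simulated libraries were drawn independently, so deviations shared within a lysate or replicate number were not included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.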

Results

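Polysome RNA was sequenced to ask which mRNAs keep ribosomes once new initiation is blocked, and whether this depends on FMRP, the RNA-binding protein encoded by Fmr1 and lost in fragile X syndrome. Brain slices from wild-type (WT) and Fmr1 knockout (KO) mice were kept for 30 min in DMSO vehicle or in 20 µM homoharringtonine (HHT), which holds ribosomes at the start of a coding sequence while those further along run off. Each lysate gave 3 kinds of library: the cleared lysate itself (input), and the pooled medium and heavy polysome fractions of a sucrose gradient. The 18 libraries form 12 groups by genotype, treatment and fraction, with 2 replicates in each of the 6 HHT groups and 1 library in each of the 6 vehicle groups.

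Estimated counts totalled 12693437 and 6298975 in the WT HHT input libraries, 9629486 and 10843607 in medium, and 7461866 and 10144452 in heavy. The KO HHT libraries held 12627946 and 13834652 counts in input, 10146917 and 10897729 in medium, and 9641398 and 11008211 in heavy. The vehicle libraries held 7690272, 6892536 and 6226237 counts in WT input, medium and heavy, and 10512901, 7076399 and 7872871 in KO. Every value below is a share of the RNA of its own fraction, because each library was made from 200 ng of RNA. Changes are log2 fold changes ± SE from edgeR, and a gene is said to have risen or fallen only where its adjusted p passed 0.05. CPM are counts scaled to a common library total. A genome position is on mm10.

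Fmr1 (chromosome X, 68678541 to 68717963) was lower in every KO library than in every WT library. In WT HHT slices it held 22.4 and 32.2 CPM in input, 18 and 23.3 in medium, and 13.9 and 18.4 in heavy. The KO HHT libraries held 8.53 and 5.07 CPM in input, 7.09 and 6.44 in medium, and 6.6 and 4.62 in heavy. The WT vehicle libraries held 25.1, 28.9 and 24.9 CPM in input, medium and heavy, against 8.04, 6.21 and 5.42 in KO. Under HHT the KO to WT change of Fmr1 was -2.00 ± 0.27 in input (adjusted p = 0.0647), -1.61 ± 0.28 in medium (adjusted p = 0.722) and -1.54 ± 0.30 in heavy (adjusted p = 0.751), none past 0.05 in the edgeR fit of 12 groups. In fits of 4 HHT libraries edgeR called Fmr1 lower in medium (adjusted p = 0.0367). With a block for replicate number these fits called it lower in all 3 fractions, in input at adjusted p = 1.41e-14. The blocked fits have 3 terms for 4 libraries, so their p-values rest mostly on spread shared over genes. The mean of the 3 fractions per lysate, chosen after the data were seen, gave -1.69 (adjusted p = 0.00189 by limma). DESeq2 called Fmr1 lower in all 3 fractions, with adjusted p = 7.99e-07, 0.00314 and 0.0319.

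**Figure D1:**
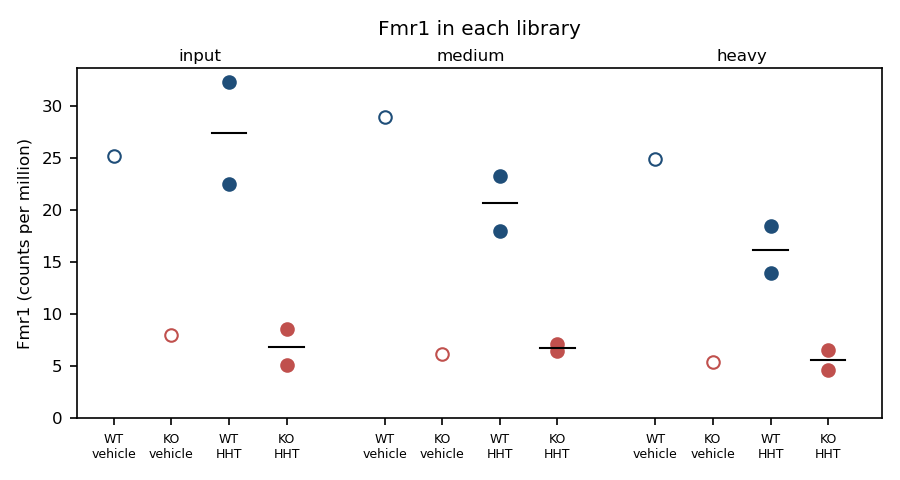
Fmr1 in CPM in each of the 18 libraries, by fraction, genotype and treatment, with open circles for vehicle, filled circles for HHT and a bar at the mean of 2 HHT replicates. The KO libraries lie between 4.62 and 8.53, and the WT libraries between 13.9 and 32.2.

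The comparison of KO with WT under HHT asks which mRNAs depend on FMRP in lysate and polysomes after the block. In input, Setd2, the histone H3 methyltransferase named by the study's chromatin question (chromosome 9, 110532597 to 110618633), stood at 0.03 ± 0.18 (adjusted p = 0.991). In medium it stood at -0.54 ± 0.18 (adjusted p = 0.999) and in heavy 0.07 ± 0.17 (adjusted p = 1), with 2 replicates per genotype. The paralogs Fxr1 and Fxr2 stayed at -0.22 ± 0.18 and 0.09 ± 0.12 in input, at -0.14 ± 0.19 and 0.01 ± 0.12 in medium, and at -0.21 ± 0.19 and -0.03 ± 0.12 in heavy, none past the threshold. With edgeR 0 genes passed in input, medium or heavy, with 679, 387 and 412 genes at unadjusted p under 0.05 against 699 by chance. With a block for replicate number, in fits of the 4 HHT libraries of a fraction, edgeR called 6, 306 and 62 genes, and without the block 0, 2 and 0. In these fits 769, 1773 and 1162 genes had unadjusted p under 0.05 with the block, and 213, 781 and 790 without it. The block leaves almost no residual degrees of freedom, so its counts rest mostly on spread shared over genes. Whether equal numbers in WT and KO share a preparation is not given in the sources used here. Across genes, deviations between replicates correlated between WT and KO at r = 0.323 in input, 0.165 in medium and 0.00332 in heavy. The edgeR fit of all libraries has no such block, so its 0 calls do not show that the genotypes are alike. DESeq2 called 4 genes in input, 2 in medium and 1 in heavy. Besides Fmr1 the DESeq2 calls were the predicted gene Gm7120, higher in KO in input and medium, and the hemoglobin genes Hba-a2 and Hbb-bs, higher in KO input, all named after their values were seen. Hba-a2 held 5.96 and 15.7 CPM in KO HHT input and 1.27 and 1.17 in WT, and reads of the near-identical alpha-globin genes cannot be assigned with certainty.

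Of the gene lists fixed in advance, no member passed over all genes between the genotypes under HHT. A selection of mRNAs bound by FMRP in published brain crosslinking data (61 listed, 61 measured) had a 0.12 median in input (camera adjusted p = 0.0034, and adjusted p = 0.899 with an estimated correlation). That median became -0.12 without WT HHT replicate 2 and -0.04 without KO HHT replicate 1. In medium the same list lay at -0.03 (camera adjusted p = 0.093, and adjusted p = 0.923 with an estimated correlation). In heavy it lay at 0.04 (camera adjusted p = 0.783, and adjusted p = 0.998 with an estimated correlation), and neither was called. The chromatin modifiers, 79 measured genes that write, read or remodel histone marks, lay at 0.01 in input (camera adjusted p = 0.584, and adjusted p = 0.993 with an estimated correlation). Their median was -0.07 in medium (camera adjusted p = 0.0054, and adjusted p = 0.923 with an estimated correlation). In heavy it was 0.02 (camera adjusted p = 0.997, and adjusted p = 0.998 with an estimated correlation). Splicing factors were lower in KO input (median -0.14, camera adjusted p = 0.000298, and adjusted p = 0.582 with an estimated correlation). Inflammatory cytokines and chemokines were lower in KO in all 3 fractions, with medians of -0.19, -0.23 and -0.18 in input, medium and heavy (camera adjusted p = 0.000906, 2.11e-06 and 0.0054, and adjusted p = 0.517, 0.291 and 0.649 with an estimated correlation). Markers of thalamus and striatum, a sign of how a slice was trimmed, lay at -0.23, -0.28 and -0.14 (camera adjusted p = 0.000645, 1.32e-05 and 0.0054, and adjusted p = 0.359, 0.291 and 0.562 with an estimated correlation), with 2 members lower in input adjusted over the list alone. Oligodendrocyte markers lay at -0.19, -0.16 and -0.09 (camera adjusted p = 0.0034, 0.000758 and 0.132, and adjusted p = 0.378, 0.291 and 0.687 with an estimated correlation). Blood cell markers, with 3 measured, were higher in KO input (median 2.54, camera adjusted p = 5.46e-06, and adjusted p = 0.141 with an estimated correlation), with 2 higher adjusted over the list alone. The 3 fractions come from the same lysates, so a list that lies on the same side in each is not seen independently in each. Of the 138 list calls made by camera with its preset correlation over all comparisons, 0 held with an estimated correlation.

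KO and WT vehicle slices, with 1 library each per fraction, are described by values alone, and a difference between 2 libraries cannot be told from a difference in their handling. Blood cell markers, 3 measured, had the largest KO minus WT medians, 1.71 in input, 1.48 in medium and 1.82 in heavy. Inflammatory genes, called lower in KO under HHT, were 0.21 in vehicle input, -0.02 in medium and -0.13 in heavy. In input the median was 0.37 for microglia markers, 0.27 for genes of protein folding in the endoplasmic reticulum (ER) and -0.10 for cytosolic ribosomal proteins. In medium the ER folding list lay at 0.30, astrocyte markers at 0.46 and the nuclear-encoded respiratory chain at -0.23. FMRP-bound mRNAs were 0.03 in input, 0.16 in medium and 0.23 in heavy.

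HHT against vehicle in input asks what the block does to the cleared lysate before any gradient. Among the largest rises were 4 genes of cell adhesion molecules, L1cam (2.5 ± 0.46), Nrcam (1.94 ± 0.40), Clstn3 (2.08 ± 0.35) and Pcdha7 (2.1 ± 0.37), where L1cam lies on chromosome X at 73853778 to 73896105 (adjusted p at most 0.00557). Also among the largest rises were the extracellular matrix protein vitronectin, Vtn (2.36 ± 0.29), the granule protein Chga (1.91 ± 0.23), the guidance cue Slit1 (1.87 ± 0.46) and the lysosomal glucosidase Gaa (2.05 ± 0.36). The sodium leak channel Nalcn rose by 1.88 ± 0.34 and the synaptic surface protein Sez6 by 1.91 ± 0.32 (adjusted p at most 0.015 for these 6). For each of these genes all 4 HHT libraries lay above both vehicle libraries. Few mRNAs fell, led by Smim1 (-0.77 ± 0.20), Ccdc186 (-0.66 ± 0.19) and the microtubule protein Map1a (-0.62 ± 0.18), with adjusted p at most 0.0346. With edgeR 1702 genes rose and 30 fell, and DESeq2 called 1514 in all. Limma on rescaled TPM called 963, and leaving out KO HHT replicate 1 gave 1143. By total counts in place of TMM 1386 rose and 230 fell, so 85.8% rose against 98.3%. The number that fell is unstable, with 96 without KO HHT replicate 1, 7 without KO HHT replicate 2, 12 without WT HHT replicate 2, and 0 in a fit of the 6 input libraries alone. Fmr1 (-0.07 ± 0.23), Fxr1 (-0.14 ± 0.15), Fxr2 (-0.04 ± 0.10) and Setd2 (-0.24 ± 0.15) did not pass.

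Among the lists given here for input, ER folding genes led by camera adjusted p, though not by median. Of these genes 22 of 34 rose (27 adjusted over the list alone), with Calr (1.57 ± 0.19), P4hb (1.50 ± 0.18), Pdia4 (1.34 ± 0.18) and Ddost (1.21 ± 0.16) at the top (median 0.78, camera adjusted p = 8.83e-15, and adjusted p = 0.185 with an estimated correlation). Markers of vessels followed, where 13 of 20 rose (17 adjusted over the list alone), including the tight junction gene Cldn5 (2.03 ± 0.31) and the cadherin Cdh5 (1.55 ± 0.24; median 0.99, camera adjusted p = 2e-10, and adjusted p = 0.185 with an estimated correlation). Of microglia markers 12 of 18 rose (15 adjusted over the list alone), with Cx3cr1 at 1.06 ± 0.20 (median 0.91, camera adjusted p = 1.21e-08, and adjusted p = 0.359 with an estimated correlation). Of inflammatory genes 11 of 24 rose (13 adjusted over the list alone), with the chemokine Ccl2 at 1.64 ± 0.23 and the receptor Cd14 at 1.24 ± 0.20 (median 0.69, camera adjusted p = 1.54e-08, and adjusted p = 0.185 with an estimated correlation). Astrocyte markers were higher as a list, with Clu at 1.40 ± 0.17 (median 0.70, camera adjusted p = 0.000206, and adjusted p = 0.185 with an estimated correlation). Oligodendrocyte markers followed, with Mag at 1.42 ± 0.19 (median 0.42, camera adjusted p = 0.00114, and adjusted p = 0.198 with an estimated correlation). Oligodendrocyte precursor markers were higher too, with Pdgfra at 1.49 ± 0.25 (median 0.57, camera adjusted p = 0.00163, and adjusted p = 0.185 with an estimated correlation). So were choroid plexus markers, with Ttr at 1.22 ± 0.23 (median 0.49, camera adjusted p = 0.00611, and adjusted p = 0.427 with an estimated correlation). Of thalamus and striatum markers 5 of 18 rose (8 adjusted over the list alone), led by the opioid precursor Penk at 1.84 ± 0.23 (median 0.22, camera adjusted p = 0.0113, and adjusted p = 0.387 with an estimated correlation). Of inhibitory neuron markers 4 of 18 rose (7 adjusted over the list alone), among them somatostatin, Sst, at 1.12 ± 0.19 (median 0.37, camera adjusted p = 0.0492, and adjusted p = 0.427 with an estimated correlation). Chromatin modifiers were lower as a list (median -0.15, camera adjusted p = 8.79e-08, and adjusted p = 0.481 with an estimated correlation), with 0 members past the threshold over all genes or over the list alone. Of FMRP-bound mRNAs 10 of 61 rose and 2 fell (11 and 3 adjusted over the list alone), among them App (1.70 ± 0.23), while the list's median was -0.13, its mean 0.13 and its direction in camera down (camera adjusted p = 0.196, and adjusted p = 0.942 with an estimated correlation). Autism risk genes also had a median of -0.14 beside a mean of 0.03, with camera calling them lower (camera adjusted p = 0.0108, and adjusted p = 0.797 with an estimated correlation). Ribosomal proteins did not move as a list (median -0.01, camera adjusted p = 0.0832, and adjusted p = 0.942 with an estimated correlation).

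Genes whose protein carries a predicted hydrophobic segment, such as a signal peptide or membrane span, made up 36.2% of the genes matched to a coding sequence and 92.0% of the 1694 matched genes that rose in input. Their median change in input was 0.39, against -0.06 for the other genes. In medium the medians were 0.50 and -0.15, and in heavy 0.68 and -0.18.

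**Figure D2:**
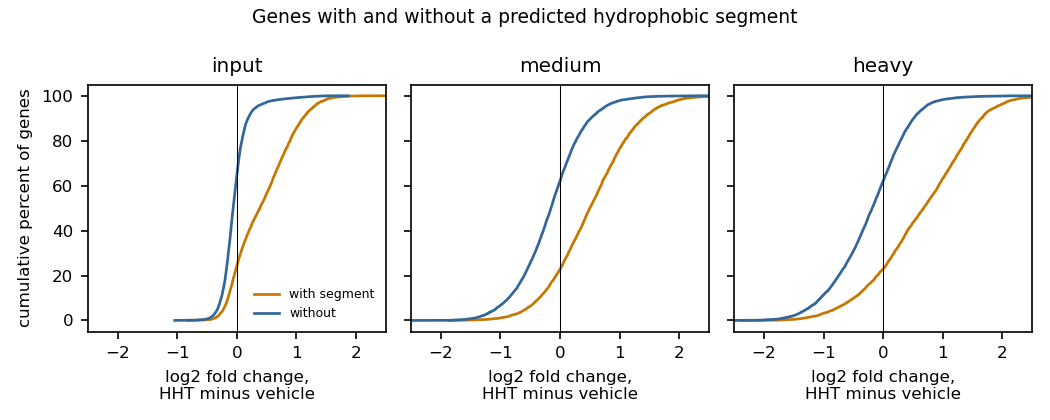
Cumulative percent of genes by log2 fold change of HHT minus vehicle in input, medium and heavy, for 4902 genes with and 8621 genes without a predicted hydrophobic segment. The curve of genes with a segment lies to the right in each fraction.

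KO slices alone gave 0 genes in input with edgeR and WT slices alone 956, each with 2 HHT libraries against 1. The difference between the genotypes, tested as genotype × treatment, gave 0 genes in input, medium and heavy, with 214, 187 and 104 at unadjusted p under 0.05, and 0 by DESeq2 in each. Setd2 had an interaction of -0.67 ± 0.33 in medium (adjusted p = 0.999), and Fmr1 -0.35 ± 0.47 in input, 0.60 ± 0.50 in medium and 0.65 ± 0.54 in heavy (adjusted p at least 0.999). As lists in input, FMRP-bound mRNAs had an interaction with median 0.10, camera adjusted p = 0.0332, and adjusted p = 0.801 with an estimated correlation. Ribosomal proteins (median 0.12, camera adjusted p = 0.00434, and adjusted p = 0.801 with an estimated correlation) and the respiratory chain (median 0.10, camera adjusted p = 0.0112, and adjusted p = 0.801 with an estimated correlation) lay on the same side, and all 3 medians changed sign when single lysates were left out.

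In the medium fraction, HHT against vehicle shows which mRNAs gain or lose share among middle-sized polysomes. Among the largest rises were the adhesion and axon guidance genes L1cam (3.26 ± 0.48), Nrcam (3.13 ± 0.43), Slit1 (2.96 ± 0.50) and Chl1 (2.72 ± 0.40) (adjusted p at most 0.000436). The calcium pump Atp2b3 (2.88 ± 0.39), the receptor phosphatase Ptprz1 (2.75 ± 0.38) and the NMDA receptor subunit Grin1 (2.61 ± 0.34) rose with them (adjusted p at most 0.000157). Among the largest falls were the fatty acid carrier Fabp5 (-1.95 ± 0.20), the proteasome subunits Psmb4 (-1.93 ± 0.18) and Psmb6 (-1.86 ± 0.19), the transcription regulator Id3 (-1.86 ± 0.19), the GTPase Rhoc (-1.87 ± 0.23) and the mitochondrial protein Chchd2 (-1.84 ± 0.17), with adjusted p at most 0.000107. Setd2 rose by 0.77 ± 0.17 (adjusted p = 0.00203), while Fmr1 (-0.18 ± 0.25), Fxr1 (-0.06 ± 0.17) and Fxr2 (-0.03 ± 0.10) did not pass. With edgeR 3551 genes rose and 3011 fell, 4 libraries against 2, and KO slices alone gave 2655 in all. By total counts 2987 rose and 3728 fell, and by limma on rescaled TPM 4100 and 2450.

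Several lists were called higher or lower in medium. Of FMRP-bound mRNAs 44 of 61 rose and 2 fell (47 and 2 adjusted over the list alone), with App (2.40 ± 0.24) and the spectrin Sptan1 (1.3 ± 0.18) among them (median 0.75, camera adjusted p = 3.25e-08, and adjusted p = 0.559 with an estimated correlation). Of chromatin modifiers 39 of 79 rose and 3 fell (41 and 3 adjusted over the list alone), with the demethylase Kdm5b (1.45 ± 0.17) and the remodellers Smarca4 (1.44 ± 0.18) and Chd4 (1.39 ± 0.17) up and the deacetylase Hdac3 (-1.07 ± 0.12) down (median 0.41, camera adjusted p = 3.51e-05, and adjusted p = 0.574 with an estimated correlation). Their median lay at percentile 87.9 of lists matched on coding length and hydrophobic segment (95% between 0.22 and 0.46), within what such genes show. The median of FMRP-bound mRNAs lay at percentile 99.9 of lists matched to them in the same way (95% between 0.31 and 0.64). No other list was matched here, and coding length correlated with this change across genes (Spearman 0.47). Of autism risk genes 29 of 48 rose and 1 fell (33 and 1 adjusted over the list alone), among them Pogz (1.04 ± 0.12; median 0.59, camera adjusted p = 2.28e-06, and adjusted p = 0.559 with an estimated correlation). ER folding genes were higher as well, with Canx at 1.82 ± 0.21 (median 0.76, camera adjusted p = 1.72e-05, and adjusted p = 0.498 with an estimated correlation). Astrocyte markers were higher, with Slc1a3 at 1.87 ± 0.20 (camera adjusted p = 0.000966, and adjusted p = 0.498 with an estimated correlation). Of ribosomal proteins 68 of 78 fell (69 adjusted over the list alone), such as Rps3 (-1.31 ± 0.16; median -0.88, camera adjusted p = 8.61e-19, and adjusted p = 0.498 with an estimated correlation). Of the nuclear-encoded respiratory chain 53 of 61 fell (57 adjusted over the list alone), led by Ndufab1 (-1.81 ± 0.16; median -1.07, camera adjusted p = 2.49e-19, and adjusted p = 0.498 with an estimated correlation). Of the proteasome 26 of 31 fell (26 adjusted over the list alone) (median -0.79, camera adjusted p = 5.52e-09, and adjusted p = 0.498 with an estimated correlation). Hippocampal neuron markers were higher (median 0.60, camera adjusted p = 0.023, and adjusted p = 0.498 with an estimated correlation), with Wfs1 at 1.79 ± 0.22.

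In the heavy fraction, where the most loaded mRNAs sediment, HHT against vehicle asks which mRNAs gain or lose share of the largest polysomes. Among the largest rises were L1cam (3.34 ± 0.48), Tenm2 (3.31 ± 0.46), Scn2a1 (3.08 ± 0.46), Scn8a (2.85 ± 0.33) and Cntnap2 (2.91 ± 0.34) and the matrix protein Tnr (3.26 ± 0.57), with adjusted p at most 0.000316. Among the largest falls were the tubulin Tuba1c (-2.51 ± 0.19), the aldolase Aldoc (-2.33 ± 0.20), the cytokine Il1b (-2.27 ± 0.27), annexin Anxa2 (-2.02 ± 0.21) and Plek (-2.11 ± 0.15), with adjusted p at most 2.13e-05. Fxr1 fell by 1.06 ± 0.16 (adjusted p = 8.2e-05) and Fxr2 by 0.51 ± 0.10 (adjusted p = 0.000846), while Fmr1 (-0.28 ± 0.27) and Setd2 (0.24 ± 0.15) did not pass. With edgeR 3781 genes rose and 3451 fell. The share that rose, 52.3%, depends on scaling: RLE factors gave 44.0%, DESeq2 45.0%, total counts 55.6% and limma on rescaled TPM 69.3%.

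Of FMRP-bound mRNAs 40 of 61 rose and 3 fell (41 and 4 adjusted over the list alone), with the synaptic adhesion gene Nlgn2 (1.78 ± 0.18) and the calcium channel Cacna1a (2.07 ± 0.23) among them (median 0.93, camera adjusted p = 1.02e-06, and adjusted p = 0.829 with an estimated correlation). Chromatin modifiers were divided, as 22 of 79 rose and 17 fell (20 and 16 adjusted over the list alone), with the methyltransferases Kmt2a (1.47 ± 0.22) and Kmt2c (1.21 ± 0.17) up and Hdac2 (-1.19 ± 0.14) down (median 0.05, camera adjusted p = 0.944, and adjusted p = 0.986 with an estimated correlation). Of splicing factors 5 of 68 rose and 43 fell (5 and 44 adjusted over the list alone), led by Hnrnpk (-1.81 ± 0.12) and Hnrnpa2b1 (-1.96 ± 0.15; median -0.70, camera adjusted p = 2.03e-09, and adjusted p = 0.424 with an estimated correlation). Of translation factors 28 of 46 fell (29 adjusted over the list alone), with Eef1a2 at -1.34 ± 0.11 and Eif4a1 at -1.39 ± 0.14 (median -0.62, camera adjusted p = 2.31e-06, and adjusted p = 0.562 with an estimated correlation). Of proteasome genes 29 of 31 fell (30 adjusted over the list alone) (median -0.99, camera adjusted p = 4.72e-11, and adjusted p = 0.562 with an estimated correlation). Of chaperones 3 of 20 rose and 15 fell (3 and 15 adjusted over the list alone), with Hsph1 at -1.16 ± 0.10 (median -0.95, camera adjusted p = 0.000138, and adjusted p = 0.424 with an estimated correlation). Of immediate early genes 7 of 44 rose and 22 fell (7 and 22 adjusted over the list alone), with Egr1 at -1.04 ± 0.11 and Fos at -0.82 ± 0.10 (median -0.39, camera adjusted p = 0.0115, and adjusted p = 0.424 with an estimated correlation). Integrated stress response genes lay at -0.43 (camera adjusted p = 0.0909, and adjusted p = 0.829 with an estimated correlation), with the tRNA synthetase Nars (-1.46 ± 0.11) and the asparagine synthetase Asns (-1.51 ± 0.14) down. ER folding genes were higher, with Ssr1 at 1.55 ± 0.16 (median 0.96, camera adjusted p = 7.91e-05, and adjusted p = 0.774 with an estimated correlation). Oligodendrocyte markers were higher, with Cldn11 at 1.58 ± 0.17 (median 0.94, camera adjusted p = 0.00448, and adjusted p = 0.424 with an estimated correlation). Ribosomal protein mRNAs, which fell in medium, lay at -0.11 in heavy (camera adjusted p = 0.0909, and adjusted p = 0.836 with an estimated correlation).

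**Figure D3:**
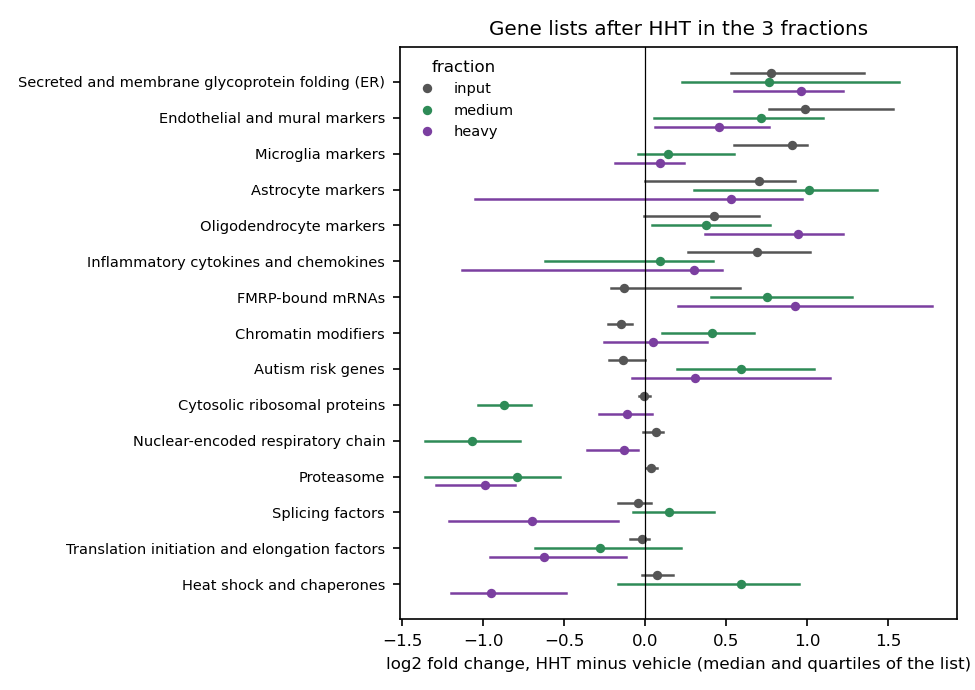
Median log2 fold change of HHT minus vehicle for 15 gene lists in input, medium and heavy, with lines from the lower to the upper quartile of the members. FMRP-bound mRNAs lie at -0.13, 0.75 and 0.93, and the proteasome at 0.04, -0.79 and -0.99.

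Taking input into account, the HHT to vehicle difference in medium/input asks which mRNAs gain or lose share among middle-sized polysomes relative to the lysate. A gain can also come from mRNAs that left the heavy pool, so it does not by itself show that an mRNA stayed. It followed coding length, with medians of -0.42, -0.23, -0.04, 0.10 and 0.38 over 5 groups of genes from shortest to longest, and the lists given here were not matched on length. The microtubule-associated Map1b (chromosome 13, 99421446 to 99516540) rose by 2.12 ± 0.36 and Map1a by 1.92 ± 0.26, with the splicing core protein Prpf8 (2.20 ± 0.37), Zc3h13 (2.25 ± 0.39), the polymerase subunit Polr2a (1.77 ± 0.22) and clathrin, Cltc (1.74 ± 0.28), adjusted p at most 0.00428. Setd2 rose by 1.014 ± 0.22 (adjusted p = 0.00946). Psmb4 (-2.12 ± 0.27), Ndufab1 (-2.07 ± 0.23), Fabp5 (-2.03 ± 0.30) and Id3 (-1.98 ± 0.27) fell, adjusted p at most 0.00317. Of chromatin modifiers 35 of 79 rose and 1 fell (41 and 2 adjusted over the list alone), with Smarca4 (1.73 ± 0.23), Asxl1 (1.37 ± 0.20) and Kdm4b (1.29 ± 0.19) in front (median 0.60, camera adjusted p = 2.94e-14, and adjusted p = 0.448 with an estimated correlation). Of FMRP-bound mRNAs 21 of 61 rose (26 adjusted over the list alone), with Map2 (1.59 ± 0.22) and Nav1 (1.51 ± 0.25) beside the Map1 genes (median 0.65, camera adjusted p = 2.47e-12, and adjusted p = 0.448 with an estimated correlation). Of autism risk genes 18 of 48 rose and 1 fell (22 and 1 adjusted over the list alone) (median 0.59, camera adjusted p = 5.61e-12, and adjusted p = 0.448 with an estimated correlation). Splicing factors were higher (median 0.26, camera adjusted p = 0.000179, and adjusted p = 0.448 with an estimated correlation). In the respiratory chain 45 of 61 fell (52 adjusted over the list alone) (median -1.15, camera adjusted p = 2.63e-23, and adjusted p = 0.448 with an estimated correlation). Among ribosomal proteins 52 of 78 fell (64 adjusted over the list alone) (median -0.87, camera adjusted p = 7.74e-19, and adjusted p = 0.448 with an estimated correlation). With edgeR 990 genes rose and 1425 fell, 1007 in all without KO HHT replicate 2, 1309 without WT HHT replicate 2, and 0 in KO slices alone against 818 in WT slices alone. The share that rose was 41.0%, against 41.3% by total counts, 46.9% by DESeq2 and 63.9% by limma on rescaled TPM.

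The same difference in heavy/input asks the same of the largest polysomes. Over 5 groups of genes by coding length its median was 0.14, -0.03, -0.15, -0.19 and 0.11 from shortest to longest. The ubiquitin ligases Birc6 (2.21 ± 0.31), Herc1 (2.13 ± 0.33) and Mycbp2 (2.03 ± 0.35), the dynein heavy chain Dync1h1 (2.21 ± 0.45), Map1b (2.12 ± 0.36) and the NMDA receptor subunit Grin2b (2.09 ± 0.62) rose, adjusted p at most 0.0232. Tuba1c (-2.83 ± 0.27), Hmox1 (-2.43 ± 0.23), Aldoc (-2.38 ± 0.30) and Il1b (-2.61 ± 0.38) fell, adjusted p at most 0.000388. Fxr1 fell by 0.91 ± 0.22 (adjusted p = 0.00831), and Setd2 (0.49 ± 0.22, adjusted p = 0.112) did not pass. Of FMRP-bound mRNAs 35 of 61 rose and 1 fell (39 and 1 adjusted over the list alone), with Macf1 (1.69 ± 0.26), Herc2 (1.9 ± 0.31) and Pclo (1.95 ± 0.32) prominent (median 0.82, camera adjusted p = 4.26e-10, and adjusted p = 0.528 with an estimated correlation). Chromatin modifiers were higher as a list (median 0.18, camera adjusted p = 0.0162, and adjusted p = 0.704 with an estimated correlation), with Ash1l (1.6 ± 0.27) and Trrap (2.01 ± 0.37) up. That median lay at percentile 25.6 of lists matched on coding length (95% between 0.08 and 0.39), so the list was no higher than genes of its length. Dendritic and postsynaptic mRNAs were higher too (median 0.47, camera adjusted p = 0.00257, and adjusted p = 0.564 with an estimated correlation), with Homer1 at 1.45 ± 0.21. Of splicing factors 36 of 68 fell (39 adjusted over the list alone) (median -0.67, camera adjusted p = 8.83e-08, and adjusted p = 0.528 with an estimated correlation). Of chaperones 13 of 20 fell (14 adjusted over the list alone) (median -1.06, camera adjusted p = 1.19e-06, and adjusted p = 0.177 with an estimated correlation). Inflammatory genes were lower, with Il1a at -2.27 ± 0.24 (median -0.57, camera adjusted p = 1.78e-05, and adjusted p = 0.528 with an estimated correlation). Microglia markers were lower, with Ctss at -1.47 ± 0.32 (median -0.90, camera adjusted p = 0.000828, and adjusted p = 0.564 with an estimated correlation). With edgeR 1762 genes rose and 2279 fell. The share that rose was 43.6%, against 36.7% with RLE factors, 38.7% by DESeq2, 60.4% by total counts and 75.5% by limma on rescaled TPM. WT slices alone gave 1706 genes and KO slices alone 1391.

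Whether loss of FMRP changes these shares was asked by the KO to WT difference in medium/input and heavy/input under HHT, 2 lysates per genotype. Setd2 was -0.57 ± 0.25 in medium/input (adjusted p = 1) and 0.04 ± 0.25 in heavy/input (adjusted p = 1). Fmr1 was 0.38 ± 0.39 and 0.45 ± 0.40, Fxr1 0.08 ± 0.26 and 0.01 ± 0.26, and Fxr2 -0.07 ± 0.17 and -0.12 ± 0.17, none past the threshold. In medium/input edgeR called 0 genes, with 259 at unadjusted p under 0.05 and 0 called by DESeq2. In heavy/input it called 1 gene (448 at unadjusted p under 0.05), Lrch4, named after its values were seen. Lrch4, a leucine-rich repeat gene (chromosome 5, 137629121 to 137641099), was 3.06 ± 0.40 (adjusted p = 0.0451), at a mean of 3.91 CPM, and the call was lost with RLE factors, with the lysate as a block and without each of the 4 HHT lysates in turn. DESeq2 called Lrch4 alone (adjusted p = 0.0262).

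As lists, FMRP-bound mRNAs were lower in KO in medium/input (median -0.14, camera adjusted p = 4.65e-05, and adjusted p = 0.981 with an estimated correlation). Chromatin modifiers were lower too (median -0.12, camera adjusted p = 0.00829, and adjusted p = 0.981 with an estimated correlation). Autism risk genes were lower (median -0.13, camera adjusted p = 0.0146, and adjusted p = 0.981 with an estimated correlation), with a median of -0.01 without KO HHT replicate 1. Splicing factors were higher in KO in medium/input (median 0.08, camera adjusted p = 0.0351, and adjusted p = 0.981 with an estimated correlation). They were higher in heavy/input as well (median 0.16, camera adjusted p = 0.000434, and adjusted p = 0.918 with an estimated correlation). FMRP-bound mRNAs were not called in heavy/input (median -0.07, camera adjusted p = 0.258, and adjusted p = 0.918 with an estimated correlation). Nor were chromatin modifiers (median -0.01, camera adjusted p = 0.723, and adjusted p = 0.918 with an estimated correlation). No member of these lists passed in either difference, over all genes or adjusted over the list alone.

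The composition of the medium fraction against input under HHT, 4 libraries against 4, describes which mRNAs the pool holds. The sodium pump subunit Atp1b2 (1.06 ± 0.16), and the BMP antagonist Nog (1.03 ± 0.16) were enriched, adjusted p at most 0.000656. Among the most depleted were the nuclear noncoding RNA Malat1 (-1.94 ± 0.24), Cdr1 (-1.76 ± 0.20), ferritin Fth1 (-1.79 ± 0.14) and Rps12 (-1.84 ± 0.18), adjusted p at most 0.000163. Of ribosomal proteins 78 of 78 fell (78 adjusted over the list alone) (median -1.36, camera adjusted p = 1.6e-50, and adjusted p = 0.261 with an estimated correlation). Of nuclear noncoding RNAs 8 of 11 fell (9 adjusted over the list alone), with Meg3 at -1.49 ± 0.17 (median -1.35, camera adjusted p = 3.05e-05, and adjusted p = 0.261 with an estimated correlation). The snoRNA host genes, with 10 measured, were lower (median -0.98, camera adjusted p = 0.00165, and adjusted p = 0.261 with an estimated correlation), led by Snhg6 (-1.67 ± 0.20). Presynaptic vesicle genes lay at 0.09 (camera adjusted p = 0.0674, and adjusted p = 0.287 with an estimated correlation), with Cplx2 at 0.62 ± 0.09. Excitatory neuron markers lay at -0.06 (camera adjusted p = 0.896, and adjusted p = 0.9 with an estimated correlation), with Lmo4 at 0.78 ± 0.11. With edgeR 1866 genes were higher and 2379 lower, 1261 in all without KO HHT replicate 2 and 1626 without WT HHT replicate 2. The share that was higher, 44.0%, was 33.2% by total counts, 50.5% with RLE factors, 51.9% by DESeq2 and 52.7% by limma on rescaled TPM.

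The heavy fraction against input under HHT, also 4 libraries against 4, describes the pool of the largest polysomes. Grin2b (2.30 ± 0.33, chromosome 6, 135713233 to 136173511), Mycbp2 (2.23 ± 0.21), Herc2 (2.19 ± 0.18), Trrap (2.18 ± 0.22), Pclo (2.15 ± 0.19) and Dst (2.09 ± 0.17) were enriched, adjusted p at most 7.68e-05. Rps12 (-2.19 ± 0.19), Igf2 (-2.18 ± 0.18), the chemokines Ccl4 (-2.16 ± 0.18) and Cxcl2 (-1.95 ± 0.17) and Rpl35a (-2.1 ± 0.20) were depleted, adjusted p at most 3.15e-06. Setd2 was enriched by 0.98 ± 0.13 (adjusted p = 2.83e-05). Of FMRP-bound mRNAs 57 of 61 rose (58 adjusted over the list alone), with Shank3 (1.29 ± 0.09) and Nisch (1.6 ± 0.12) the clearest (median 1.38, camera adjusted p = 1.88e-22, and adjusted p = 0.312 with an estimated correlation). Of chromatin modifiers 67 of 79 rose and 3 fell (67 and 3 adjusted over the list alone), among them Kmt2d (1.96 ± 0.13; median 0.74, camera adjusted p = 2.98e-17, and adjusted p = 0.312 with an estimated correlation). Of autism risk genes 42 of 48 rose (42 adjusted over the list alone) (median 0.97, camera adjusted p = 3.29e-14, and adjusted p = 0.312 with an estimated correlation). All 78 ribosomal protein mRNAs were lower, over all genes and adjusted over the list alone (median -1.59, camera adjusted p = 3.08e-30, and adjusted p = 0.312 with an estimated correlation). Among microglia markers 18 of 18 fell (18 adjusted over the list alone) (median -1.44, camera adjusted p = 1.47e-08, and adjusted p = 0.312 with an estimated correlation). Immediate early genes were divided (median 0.13, camera adjusted p = 0.167, and adjusted p = 0.343 with an estimated correlation), with Jun up by 1.57 ± 0.09. Fmr1 was lower (-0.50 ± 0.20, adjusted p = 0.0452). None of the lists above was matched on coding length here, and length correlated with this change across genes (Spearman 0.643). Median coding length was 5427 nt for FMRP-bound mRNAs and 4863 nt for chromatin modifiers. Length may therefore account for part or all of the list medians. With edgeR 3860 genes were higher and 4250 lower. The share that was higher, 47.6%, was 28.1% by total counts, 49.9% with RLE factors, 51.5% by DESeq2 and 52.8% by limma on rescaled TPM.

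With genes put in 5 groups of equal size by coding length, the median heavy to input change ran from -0.65 in the shortest genes (up to 789 nt) to 0.59 in the longest (at least 2607 nt), and the medium to input change from -0.25 to 0.10. HHT against vehicle in medium ran from -0.42 to 0.43, whereas in heavy it was 0.17, 0.05, -0.06, -0.20 and 0.07 from shortest to longest. The lists given for medium against input were not matched on length either (Spearman 0.278 across genes).

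**Figure D4:**
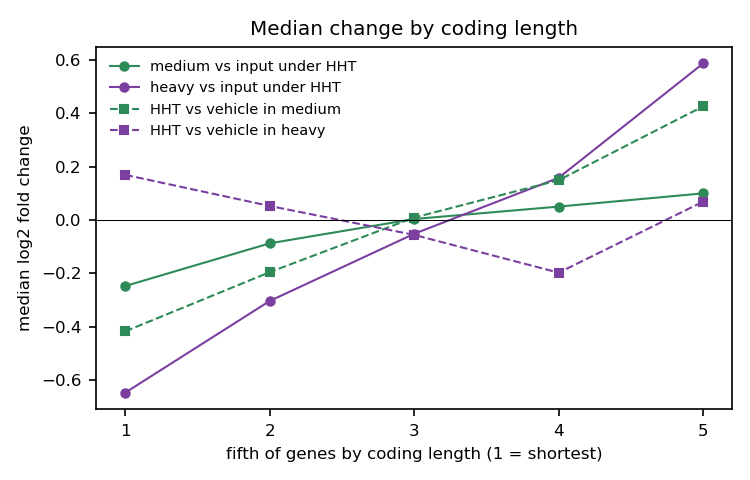
Median log2 fold change for 5 groups of genes ordered by coding length, for medium and heavy against input under HHT (solid lines) and for HHT against vehicle in medium and heavy (dashed lines), with 2704 or 2705 genes per point. The heavy to input line climbs from -0.65 to 0.59.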

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

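The look at the neighbouring gene Gm20605 was chosen after the result was seen, as was the test on rescaled TPM. Lrch4 was singled out because its heavy/input ratio differed between the genotypes by a test of that difference, 3.055 on the log2 scale under HHT (adjusted p = 0.0451 with edgeR). In KO HHT slices it held 1.58 and 2.15 CPM in input and 4.98 and 4.73 in heavy, and in WT HHT slices 4.86 and 5.54 in input and 1.95 and 1.3 in heavy. The vehicle libraries, not used in that difference, held 1.35 and 5.27 in KO input and heavy, against 3.06 and 1.29 in WT. The annotated gene Gm20605 covers 137629175 to 137642899 on chromosome 5, the same strand as Lrch4 at 137629121 to 137641099, so reads of the shared part are divided between them by estimation. Gm20605 held a mean of 15.7 CPM, and its own heavy/input difference between the genotypes was -0.67 ± 0.29. No explanation was tested. The call was kept by DESeq2 (3.06, adjusted p = 0.0262), total counts (3.07, adjusted p = 0.0348), a fit of the 12 HHT libraries (3.06, adjusted p = 0.0471) and limma on rescaled TPM (2.46, adjusted p = 0.0217), the last chosen after the data were seen. With RLE factors the smallest adjusted p over genes was 0.0505 and with a lysate block 0.0769, and the 4 fits that each left out 1 HHT lysate called 0 genes.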

How the results depend on the processing

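The tests on rescaled TPM, on lysate means and with single HHT replicates, and the lysate block for lists, were chosen after the results were seen. The 12 comparison counts other than KO against WT kept their side of the threshold and stayed within 1.5 times under RLE factors, total counts and DESeq2, except the single gene in heavy/input, 0 with RLE. The filter removed no gene, so its absence tests nothing. DESeq2 called 4, 2 and 1 genes for KO against WT in input, medium and heavy. A block for replicate number gave 6, 306 and 62 in fits of 4 libraries, which leave almost no residual degrees of freedom. Whether equal numbers share a preparation is not given in the sources used here. The 4 HHT libraries of medium alone gave 2. Means per lysate gave 5 genes, the same count for each fraction since it is 1 test. A lysate block gave 0 genes for the KO to WT difference in heavy/input. In the 12 HHT libraries that block gave 5146 genes for medium against input and 8540 for heavy against input. The main fit gave 4245 and 8110. Limma on rescaled TPM gave 2 genes for KO against WT in input and 963 for HHT against vehicle in input. The cause was not tested for these.

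With fewer libraries, WT and KO slices alone gave 956 and 0 genes for HHT against vehicle in input, and KO alone 2655 in medium. For the HHT to vehicle difference in medium/input they gave 818 and 0, and in heavy/input 1706 and 1391. Each HHT lysate left out in turn gave, for HHT against vehicle in input, 1143 to 1833 genes, for the difference in medium/input 1007 to 2276, and for medium against input 1261 to 3520. It gave 0 to 2 for KO against WT in input and 0 to 0 for the KO to WT difference in heavy/input. The lone replicate left in a group was then assumed to vary like the other groups. The sign with HHT replicate 1 or 2 alone, 100% the same in all 3 fractions, tests nothing, since the genes were called with both replicates and the same vehicle libraries.

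Of 420 list tests, 138 were called with the preset correlation, 0 with an estimated correlation and 97 with fry. Fry tests a shared shift of the members against no change, whereas camera tests the members against the other genes. Their counts therefore answer different questions. An estimated correlation widens the error of correlated lists. Leaving out a lysate turned 4 list medians over. FMRP-bound mRNAs ran from -0.123 without WT HHT replicate 2, past -0.0405 without KO HHT replicate 1, to 0.357 in KO against WT in input. In genotype × treatment in input they ran from -0.146 and -0.136 without these lysates to 0.335. In that interaction, without WT HHT replicate 1 or KO HHT replicate 2, ribosomal proteins went to -0.0892 or -0.195, with 0.411 the highest. The respiratory chain went to -0.0951 or -0.177, with 0.38 the highest. Autism risk genes ran from -0.215 to -0.0126 in the KO to WT difference in medium/input, where only the direction in camera turned over. The cause was not tested. Named genes gave 792 results, of which each alternative covered 3 to 792, and 0 reversed. Apart from Fmr1 in KO against WT, these had passed in the main fit on the same libraries, so 0 reversals say little. In KO slices alone 249 of 535 weakened, and in WT slices alone 94 of 535.

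Total counts moved the median of all genes in heavy against input from -0.04 to -0.28, in HHT against vehicle in input from -0.00 to -0.11, and in the HHT to vehicle difference in heavy/input from 0.01 to 0.16. Rescaled TPM moved it to 0.24 for HHT against vehicle in heavy, 0.18 for the difference in medium/input and 0.31 in heavy/input. Shares of rising genes are relative to those shifts. Of 1.5-fold differences simulated between genotypes in input 12% were recovered and of 4-fold ones 100%, with 200 changed genes. Comparisons with few changed genes were not simulated, and adjustment is harsher there. Simulated libraries were drawn independently, without deviations shared within a lysate or replicate number. The recovered shares therefore need not hold for the real libraries.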

Other observations

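The explanations were tested after the patterns were seen, each with its prediction written before its own test, and the match on both coding length and segment was chosen after the result of the match on length was seen. In the cleared lysate after HHT, the genes that rose held a share with a predicted hydrophobic segment 2.54 times that of all genes (92.0% against 36.2%). The tables argue against more glial and vascular cells as the whole cause: markers of these cells without a segment had a median of 0.0249 (22 genes, 4 rose) against 0.84 with one (64 genes, 41 rose), although 3 of 4 microglia markers without a segment rose. Bins of GC content and coding length left the difference between genes with and without a segment at 0.455, against 0.448 without bins. A hypothesis is that mRNAs held on membranes pellet before detergent is added and may return to the supernatant once HHT lets their ribosomes run off. Relative to input, genes with a segment had HHT to vehicle medians of 0.0954 in medium and 0.252 in heavy. The other genes had -0.0959 and -0.131. These medians do not decide whether run-off differed between genes with and without a segment. mRNAs that pelleted in vehicle slices would be missing from input and fractions alike, so the vehicle ratios are not a full baseline. Both more run-off and run-off that differs little stay open, since amounts were not measured. RNA of the pellet and the share of bound ribosomes were not measured here, and with HHT in the slice a change of transcription or decay stays open too.

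FMRP-bound mRNAs had a heavy/input difference between HHT and vehicle of 0.82 at the median, at percentile 100 of 10000 random lists matched on coding length (with 95% of those lists between 0.07 and 0.42). Lists matched on both coding length and a hydrophobic segment left it at percentile 100 as well (95% between 0.01 and 0.36), with medians of 1.12 for the 32 members with a segment and 0.47 for the 29 without. In these libraries the list thus stands apart from genes of its length and segment. The list is a selection, so this need not hold for all mRNAs that FMRP binds. Such percentiles carry no spread between libraries, and the list's call in this comparison is lost with an estimated correlation (adjusted p = 0.528). Slower or stalled ribosomes on these mRNAs may account for it, which is a hypothesis, since ribosome positions were not measured here and the lists were not matched on expression. The difference is a mean over WT and KO slices. The list's KO to WT difference in heavy/input under HHT was not called, so a dependence on FMRP is not shown.

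The lower medium/input ratio of FMRP-bound mRNAs in KO slices (median -0.135) lay at percentile 3.54 of lists matched on coding length, and that of chromatin modifiers (-0.115) at percentile 13.6. Both lie within the central 95% of such lists (-0.141 to -0.0361 and -0.134 to -0.0432), so a trend with coding length could account for the size of both ratios. For FMRP-bound mRNAs the parts differ: in KO against WT in input their median of 0.116 lay at percentile 100 of such lists (-0.0441 to 0.0655), and in medium -0.0289 lay at percentile 81.9. Length does not give the input part, which turned negative without WT HHT replicate 2 or KO HHT replicate 1. The explanation of that list's ratio therefore stays open. Across genes the KO to WT difference in medium/input had a Spearman correlation of -0.146 with coding length, over genes that are not independent replicates, and the genotype × treatment term in medium, with 1 vehicle library per genotype, one of -0.364. An effect of FMRP on long mRNAs as such stays open, since the genotype and a shift of gradient pooling between the 2 genotypes would both follow length.

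For medium against input under HHT, the real split of the 8 libraries called 3960 genes in a fit of these libraries alone, and the highest of the other 34 splits called 8, so 1 of 35 splits, the real one, gave as many. For heavy against input the real split called 7869 genes and each other split 0, again 1 of 35. These splits exchange libraries freely, although fractions of 1 lysate are paired. Only 8 distinct splits keep each lysate on both sides, too few for the real one to stand apart at 0.05.

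On the first component of the 2000 most variable genes, with 57.9% of the variance, HHT input replicate 1 lay at -8.27 in WT and -9.42 in KO, and replicate 2 at 15.5 and 12.6. The vehicle input libraries lay at 33 in WT and 24.1 in KO. Across genes, the deviations between replicates 1 and 2 correlated between WT and KO at r = 0.323 in input, 0.165 in medium and 0.00332 in heavy, over genes that are not independent replicates.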
